A study of Mus musculus with 11 samples.

How the data were processed

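RNA was measured in 11 libraries of the tibialis anterior, a mostly fast-fibre muscle of the shin, from C57BL/6 mice aged 21 to 24 months. The muscles came from an injury model. The animals had been injected with saline (4 libraries), with serum of young mice (4 libraries) or with young serum depleted of extracellular vesicles (EVs, membrane-bound particles that cells release; 3 libraries). The labels give groups and sample numbers but do not state that each library came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. The submitters' processing notes name FastQC, STAR, DESeq2 and the mouse build mm10, without versions, roles or order.

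The deposited CPM table holds 18269 genes and 11 libraries, and the authors scaled each library to 1000000 over the genes in the table, after which an offset of 0.0001 had been added, as read from the values. The deposited TPM table holds the same genes, and the values show that the authors divided CPM by the genomic span of each gene, introns included, since span times TPM over CPM was constant to within a coefficient of variation of 0.000192%. Its totals were 288820 per library. TPM therefore weighs genes with long introns down, and CPM was used for the results. Low CPM values moved in steps worth 1 read, which placed the depth between 36.4 and 42.3 times 1e+06 reads per library. Of the values between 0.01 and 1 CPM, 75.1% to 78.8% were whole multiples of that step within 0.1 reads, too few to rebuild read counts, so no count model was fitted. Gene starts matched GENCODE M21 on mm10 for 99.4% of the 17893 symbols found there, and the end positions given here are the deposited ones minus 1. No mitochondrially encoded gene is among the genes in the tables, and Xist is not analysed here. Ddx3y, a Y-linked gene, was present in all 11 libraries.

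Genes with at least 1 CPM in at least 3 libraries were tested, which kept 13187 and removed 5082. Values were analysed as log2(CPM + 1), with a pseudocount of 1, so the fold changes of low genes are understated. limma 3.58.1 in R 4.3.3 fitted the 3 groups in 1 model over all 11 libraries, with eBayes and a trend of the variance on the mean. Tests were two-sided and adjusted by Benjamini-Hochberg at 0.05. Gene lists (46, fixed with their members) covered metabolism, fibre types, resident and immune cell types, stress, matrix and signalling. Of these, 42 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. The other 4 were not tested: the mitochondrially encoded respiratory chain genes, the neutrophil, the T and NK cell, and the skin and hair lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it, together with an exact permutation of the mean list score over the libraries. The estimated correlation had a median of 0.356 over the lists. It was 0.775 for complex I, 0.743 for complexes II to V, 0.696 for ribosomal proteins, 0.872 for adipocytes, 0.793 for slow fibre genes and -0.014 for satellite cells. For lists far above 0.01, the preset p-values are likely too small. The groups, tests, lists and most alternatives were fixed before the data were examined; the alternatives added later are named with the sensitivity results.

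Genes are named by a fixed rule. Per comparison, the 12 highest and 12 lowest log2 fold changes past the threshold with non-overlapping groups were to be named; since fewer than 6 passed in each direction, those with the smallest unadjusted p were added up to 6, and these did not pass. Up to 4 members with the largest moderated statistic were named per called list, besides a fixed set of muscle, fibrosis, fat, ageing and inflammation genes. Predicted genes and pseudogenes were counted but not named. Fixed genes below the filter were compared by an exact permutation test of CPM.

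The pipeline was tested on simulated data with 200 changed genes among 13187, using each group's own spread. For young serum against saline it recovered 70.5% of genes changed by a log2 of 1 and 95.0% of those changed by 2, with 17.1% and 14.8% of calls false. For EV-depleted serum against saline it recovered 49.5% and 95.5%, with 20.8% and 28.7% false. For young against EV-depleted serum it recovered 62.0% and 92.0%, with 10.8% and 7.54% false. These false shares exceed the nominal 5%; with equal spread in all groups they were 2.00% to 5.13%. Figures were drawn with matplotlib in Python 3.11.15.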

Results

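The data comprised 11 RNA libraries of tibialis anterior muscle from aged C57BL/6 mice: 4 after saline injection, 4 after young serum and 3 after young serum from which EVs had been depleted. Depth, read from the steps of the low CPM values, was 36.4 to 42.3 times 1e+06 reads per library. The design asks whether young serum alters gene expression in aged muscle and whether removing EVs alters that effect. The saline libraries varied most, with a median within-group SD of 0.30 on the log2 scale against 0.15 in young serum and 0.22 in EV-depleted serum. Saline replicate 4 had the highest adipocyte list score, 3.52, and an Adipoq level of 319.8 CPM, while saline replicate 6 had the highest slow fibre score, 2.15, and a Myh7 level of 944 CPM. Adipoq encodes an adipocyte hormone and Myh7 the slow myosin heavy chain. The first 2 principal components took 38.7% and 32.0% of the variance.

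In muscle given young serum, transcripts of the respiratory chain and of cytosolic ribosomal proteins were lower than in saline by camera with the preset correlation. With an estimated correlation the adjusted p was 0.870 for these and for every list called in this comparison. All 36 nuclear genes of complex I were lower, with a mean log2 difference of -0.54 ± 0.24 (SE; 4 and 4 libraries), as were all 39 genes of complexes II to V (-0.54 ± 0.29) and all 35 ribosomal protein genes (-0.63 ± 0.28). Saline replicate 6 had the highest score of these 3 lists (0.94, 1.06 and 1.10), and without it the differences were -0.31, -0.27 and -0.39. Macrophage genes (-0.65 ± 0.34, 18 of 20 lower), antigen presentation genes (-0.92 ± 0.49, 5 of 6) and haemoglobin and other red cell genes (-1.01 ± 0.43, 6 of 6) were also lower. Genes of the circadian clock (0.31 ± 0.10, 12 of 16 higher), of tendon (0.47 ± 0.21, 9 of 11) and of excitation-contraction coupling (0.22 ± 0.10, 10 of 16) were higher. Nrap, which encodes an actin-binding protein of myofibril assembly and of the myotendinous junction, stood at 953 ± 113 CPM in saline (SD, n = 4) and 1622 ± 95.9 CPM in young serum (SD, n = 4).

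Among the oxidative genes, 12 of the complex I members passed when adjusted over the list alone and 0 over all genes. Ndufb7, an accessory subunit, averaged 184 ± 69.6 CPM in saline and 107 ± 13.5 in young serum (SD). Uqcrb of complex III averaged 180 ± 26.7 and 130 ± 18.0 CPM, and 0 members of complexes II to V passed over the list alone. The fatty acid list differed by -0.24 ± 0.22, with 21 of 23 lower; the difference was -0.12 without saline replicate 6 and -0.13, -0.36 and -0.13 without young serum replicates 1, 3 and 4. With the replicate number as a block it was -0.0130, and camera's direction changed. That block in effect leaves out saline replicate 6 and young serum replicate 1, whose numbers no other library shares. In the ribosomal list, Rpl8 averaged 371 ± 59.5 and 268 ± 15.7 CPM and Rps24 369 ± 291 and 142 ± 16.3 CPM, with 799 CPM in saline replicate 6 and 174 to 293 CPM in the other saline libraries. Oxidative stress genes differed by -0.34 ± 0.15 with 15 of 22 lower, 3 of them past adjustment over the list alone (Gpx1, Prdx1 and Hmox1). Gpx1, a glutathione peroxidase, averaged 150 ± 60.8 and 62.3 ± 8.72 CPM.

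Of the immune and stromal lists, 9 macrophage and 4 antigen presentation genes passed when adjusted over the list alone and 0 over all genes. Lyz2, the macrophage lysozyme, averaged 80.2 ± 36.2 CPM in saline and 35.4 ± 16.0 in young serum, and Cd74, the class II invariant chain, 176 ± 156 and 58.4 ± 24.5. The adipocyte list differed by -1.02 ± 1.02 with 19 of 19 lower (0.18, the other direction, without both saline replicates 4 and 6), Fabp4 averaging 519 ± 685 and 105 ± 23.1 CPM, and the endothelial list by -0.27 ± 0.15 with 13 of 17 lower. Saline replicate 4 had the highest score of the adipocyte, macrophage and antigen presentation lists, with Fabp4 at 1543 CPM (125 to 256 in the other saline libraries) and Cd74 at 403 CPM (61.8 to 152). Haemoglobin genes Hba-a1 and Hba-a2, which are near-identical copies, averaged 105 ± 45.0 and 104 ± 48.5 CPM in saline and 45.3 ± 19.8 and 45.3 ± 18.2 CPM in young serum. The haemoglobin gene Hbb-bs stood at 1121 CPM in saline replicate 6 and at 79.6 to 180 CPM in the other saline libraries. The red cell score ranged from -0.30 to 1.38, in saline replicate 6, and from -1.20, in young serum replicate 1, to -0.03 in young serum.

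Among the genes higher in young serum, the clock repressor Per2 averaged 8.08 ± 2.86 CPM in saline and 17.6 ± 3.54 in young serum, and the clock output factor Hlf 13.1 ± 1.44 and 22.7 ± 4.91; both were among 4 clock genes past adjustment over the list alone. The hour of tissue collection is not given in the sources used here. A difference in hour therefore cannot be told apart from a serum effect on the clock genes. Ryr1, the calcium release channel of the sarcoplasmic reticulum, averaged 2947 ± 916 and 4988.5 ± 500.1 CPM, and Scn4a, the muscle sodium channel, 352 ± 80.3 and 561 ± 54.4. They were among 6 coupling genes past adjustment over the list alone. Saline replicate 6 was lowest for both, at 1684 and 251 CPM (3088 to 3878 and 334 to 442 in the other saline libraries). The coupling score ranged from -0.33, in saline replicate 6, to 0.10 in saline and from 0.04 to 0.16 in young serum. Whether a bias of the libraries with transcript length bears on the coupling difference was not tested. The tendon gene Chad averaged 2.91 ± 2.29 and 8.61 ± 3.90 CPM and was the 1 tendon gene past that adjustment, with 6.18 CPM in saline replicate 6 and 0.970 to 2.61 CPM in the other saline libraries. Predicted genes and pseudogenes aside, 1 of which had the smallest p of all, the smallest unadjusted p-values among higher genes belonged to Nrap (1.71-fold, mm10 chromosome 19, 56320035 to 56390037), Uaca (1.47-fold), the potassium channel Kcnc1 (1.64-fold), Pcdhga10 (1.76-fold), Rnf157 (1.54-fold) and Zfp651 (1.41-fold). Among lower genes they belonged to Kazald1 (0.526-fold), Prxl2b (0.640-fold), Pgk1 of the glycolysis list, which was not called (0.637-fold, 631 ± 52.2 against 402 ± 34.3 CPM), the replication factor Gins2 (0.228-fold), Dnase2a (0.554-fold) and Cmtm7 (0.649-fold). None of these 12 passed, the adjusted p of Nrap being 0.149 by limma.

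For single genes, limma called 0 of 13187 in this comparison (smallest adjusted p = 0.0767), with 2890 at an unadjusted p under 0.05 (1382 higher, 1508 lower) where 659 are expected by chance, and array weights called 3441. The estimate of these weights stopped before convergence. It gave saline replicate 3 a weight of 3.32, against 0.563, 0.208 and 0.295 for saline replicates 2, 4 and 6. The saline mean of that fit thus rested mostly on 1 library. Without weights, leaving out saline replicate 2 gave 251 genes and saline replicate 6 gave 1. The 2 groups did not overlap for 1605 genes (12.2%, against 2.86% by chance). Camera with the preset correlation called 13 of 42 lists, 3 higher and 10 lower, with adjusted p from 2.55e-11 (complex I) to 0.0433 (antigen presentation). All 13 had an adjusted p = 0.870 with an estimated correlation, and fry called 0 lists (smallest adjusted p = 0.312). Of the 13 calls, 9 were kept without saline replicate 2, 7 without saline replicate 4, 11 without saline replicate 6, 11 without young serum replicate 1, 12 without replicate 3 and 10 without replicate 4. Without saline replicate 4 the differences were -0.07 for adipocytes, -0.40 for macrophages, -0.53 for antigen presentation, -0.21 for oxidative stress and -0.13 for endothelial genes.

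In muscle given EV-depleted serum, slow fibre genes were higher than in saline by camera with the preset correlation (1.09 ± 0.80, SE; 4 and 3 libraries; 14 of 15 higher). With an estimated correlation the adjusted p was 0.721 for this list and 0.584 to 0.776 for all 18 lists called in this comparison. No slow fibre gene had an unadjusted p under 0.05, and the difference was 1.87 without saline replicate 6, whose score was 2.15. Also higher were the tricarboxylic acid cycle (0.21 ± 0.08, 17 of 18 higher), fatty acid (0.17 ± 0.13, 18 of 23), mitochondrial biogenesis (0.21 ± 0.09, 18 of 20), heat shock (0.22 ± 0.10, 14 of 17) and immediate early (0.27 ± 0.27, 13 of 19) lists. Immune and stromal lists were lower: macrophages (-0.68 ± 0.33), antigen presentation (-1.27 ± 0.42), B and plasma cells (-1.24 ± 0.37), mast cells (-0.97 ± 0.46), interferon response (-0.38 ± 0.17), complement (-0.55 ± 0.41), fibro-adipogenic progenitors (-0.38 ± 0.25), adipocytes (-1.07 ± 1.02) and endothelial cells (-0.22 ± 0.17). The B and plasma cell list had 5 of 14 members measured and the mast cell list 5 of 8. Igkc stood at 168 CPM in saline replicate 4 and at 3.88 to 37.7 CPM in the other saline libraries. Ighm stood at 189 CPM in saline replicate 6 and at 326 to 363 CPM in the others. Complex I (-0.24 ± 0.27), ribosomal protein (-0.54 ± 0.36) and glycolysis genes (-0.13 ± 0.08) were lower too. The immediate early difference was 0.12 without EV-depleted replicate 2, where Fos stood at 87.3 CPM against 5.81 and 7.30 in the other 2, and 0.49 without saline replicate 4. Igfn1, an immunoglobulin and fibronectin domain protein of skeletal muscle, averaged 18.8 ± 8.73 CPM in saline (SD, n = 4) and 117 ± 41.1 CPM in EV-depleted serum (SD, n = 3), a 6.27-fold difference.

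Otud1, a deubiquitinase, averaged 13.3 ± 3.004 and 46.8 ± 16.1 CPM (3.26-fold), Xirp1, an actin-binding protein of muscle attachment sites, 95.8 ± 11.1 and 189 ± 37.5 (1.94-fold), and Col22a1, a collagen of the myotendinous junction, 10.8 ± 1.99 and 21.5 ± 3.13 (1.92-fold). Nrap was 1.83-fold and Uaca 1.55-fold higher. The lower genes with the smallest p were Ufsp1 (0.504-fold), Vasp (0.571-fold), Kazald1 (0.521-fold), Dhrs7c (0.686-fold), the immunoglobulin heavy chain gene Ighm (0.451-fold) and Prxl2b (0.664-fold). In the lists, Myh7 averaged 276 ± 446 (944 CPM in saline replicate 6, 43.2 to 67.8 in the others) and 472 ± 117 CPM, Pdha1 of pyruvate dehydrogenase 460 ± 94.1 and 618 ± 39.9, Hspb7, a small heat shock protein, 293 ± 133 and 662 ± 144, and the immediate early gene Atf3 4.77 ± 0.98 and 9.30 ± 2.42. Gapdh averaged 1545 ± 252 and 1119 ± 114 CPM and was 1 of 5 glycolysis genes past adjustment over the list alone, of which Gbe1 was higher and 4 were lower. Past that adjustment were also 4 macrophage, 4 antigen presentation and 3 B and plasma cell genes; 0 passed over all genes.

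In this comparison limma called 0 genes (smallest adjusted p = 0.0684 for Igfn1, Otud1 and Nrap), with 1593 at an unadjusted p under 0.05, 856 higher and 737 lower, and 1794 with array weights. Those weights were 3.32 for saline replicate 3 and 4.19 for EV-depleted replicate 2, against 0.634 and 0.423 for EV-depleted replicates 3 and 4. Without weights, limma called 5 without saline replicate 2, 1 without saline replicate 4, 2 without saline replicate 6 and 1 without EV-depleted replicate 4. The 2 groups did not overlap for 979 genes (7.42%, against 5.71% by chance). Camera called 18 lists, 6 higher and 12 lower, with adjusted p from 2.24e-08 (ribosomal proteins) to 0.0467 (fatty acid genes); fry called 0 (smallest adjusted p = 0.103). Of the 18 calls, 15, 16, 13 and 17 were kept without saline replicates 2, 3, 4 and 6, and 16, 13 and 15 without EV-depleted replicates 2, 3 and 4. Without saline replicate 6 the difference of complex I was -0.02, of ribosomal proteins -0.30 and of fatty acid genes 0.29 (0.08 without saline replicate 3), and without saline replicate 4 that of adipocytes was -0.12 (0.13 without both saline replicates 4 and 6), of macrophages -0.44, of interferon genes -0.24, of complement -0.26 and of endothelial genes -0.08. Without EV-depleted replicate 3 it was -0.37 for complex I (-0.12 without replicate 4), -0.19 for fibro-adipogenic progenitors, -0.28 for complement and -0.14 for endothelial genes.

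Between the 2 sera, oxidative genes were lower with young serum than with EV-depleted serum by camera with the preset correlation: complexes II to V (-0.34 ± 0.18, SE; 4 and 3 libraries; 39 of 39 lower), complex I (-0.30 ± 0.17, 36 of 36), tricarboxylic acid cycle (-0.28 ± 0.11, 18 of 18) and fatty acid genes (-0.41 ± 0.18, 22 of 23). With an estimated correlation the adjusted p was 0.477 for these 4 lists and 0.321 to 0.685 for all 18 called in this comparison. Without EV-depleted replicate 3 the differences were -0.21 for complexes II to V and -0.16 for complex I. Young serum replicates 1 and 4 had fatty acid scores of -0.50 each and tricarboxylic acid scores of -0.28 and -0.26. Replicates 2 and 3 of that group had 0.05 and 0.17, and 0.09 and 0.04. EV-depleted serum had 0.16 to 0.25 for fatty acid and 0.11 to 0.25 for tricarboxylic acid genes. Slow fibre genes (-1.39 ± 0.55, 14 of 15 lower), heat shock genes (-0.26 ± 0.07, 17 of 17) and immediate early genes (-0.37 ± 0.17, 16 of 19) were lower as well, and the slow fibre score ranged from 0.71 to 1.21 in EV-depleted serum and from -1.70 to 0.80 in young serum. Acadm, a fatty acid dehydrogenase, averaged 264 ± 56.6 CPM in young serum (SD, n = 4) and 378 ± 8.38 in EV-depleted serum (SD, n = 3), and the lens and muscle chaperone Cryab 440 ± 93.6 and 796 ± 141. Further differences were those of Schwann cells (-0.33 ± 0.34) and red blood cells (-0.59 ± 0.25), lower with young serum, and of glycolysis (0.12 ± 0.06), coupling (0.09 ± 0.06), collagens (0.21 ± 0.36), basement membrane (0.18 ± 0.31), interferon (0.18 ± 0.21), complement (0.24 ± 0.35), tendon (0.23 ± 0.23), mast cells (0.40 ± 0.40) and the clock (0.13 ± 0.10), higher.

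In the clock list, 5 genes passed when adjusted over the list alone and 0 over all genes: Per2 (0.79) and Hlf (0.59) were higher with young serum, and Arntl (-0.71), Npas2 (-0.56) and Nr1d1 (-0.44) lower. Ache, the acetylcholinesterase of the neuromuscular junction, averaged 37.1 ± 4.56 CPM in young serum and 21.8 ± 2.37 in EV-depleted serum, beside 35.8 ± 7.95 in saline. Ufsp1 (1.55-fold) lies next to Ache on chromosome 5, from 137294629 to 137295665, and the strand handling of the counting is not stated, so their values are not separated with certainty. Tsc22d3 (1.32-fold), a glucocorticoid-induced gene, and Acvr1b (1.44-fold) were also higher. Igfn1 (0.321-fold, chromosome 1, 135953578 to 136006342) and Otud1 (0.476-fold) were lower with young serum, as were Tmem9 (0.601-fold), adjacent to Igfn1, Arhgap24 (0.592-fold), St3gal5 (0.647-fold) and the growth factor gene Fgf7 (0.619-fold).

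Here limma called 0 genes (smallest adjusted p = 0.99998), with 294 at an unadjusted p under 0.05 (63 higher, 231 lower), fewer than the 659 expected by chance, while array weights called 24. Those weights were 4.19 for EV-depleted replicate 2 and 0.634 and 0.423 for replicates 3 and 4. The fit pools the spread over all 11 libraries, and saline varied most (median SD 0.30, against 0.15 in young and 0.22 in EV-depleted serum). The low count may in part reflect the saline spread and does not show that the sera act alike. Groups did not overlap for 806 genes (6.11%, against 5.71% by chance). Camera called 18 lists, 9 in each direction, with adjusted p from 3.15e-15 (complexes II to V) to 0.0310 (coupling); fry called 0 (smallest adjusted p = 0.817). The exact permutation p was 0.0286 for heat shock and for immediate early genes, the smallest that 35 arrangements allow, and 0.600 for both when adjusted over the 42 lists. Of the 18 calls, 13 were kept without EV-depleted replicate 3 and 15 without replicate 4, and 14, 16, 16 and 17 without young serum replicates 1 to 4. Without EV-depleted replicate 3 the difference was -0.11 for collagens, -0.09 for basement membrane, -0.03 for complement, 0.04 for tendon, 0.14 for mast cells, 0.11 for interferon, 0.04 for coupling, 0.05 for the clock and -0.57 for Schwann cells. Without EV-depleted replicate 4 it was 0.43 for collagens, 0.44 for basement membrane, 0.41 for complement, 0.35 for tendon, 0.61 for mast cells, 0.14 for coupling, 0.22 for the clock and -0.08 for Schwann cells, and without replicate 2 -0.22 for immediate early genes. The interferon difference was 0.02 without young serum replicate 3 and 0.32 without replicate 4. Leaving out young serum replicate 1 gave -0.37 for red blood cells, 0.09 for collagens, 0.08 for complement, 0.20 for mast cells and -0.51 for Schwann cells, and leaving out replicate 4 gave 0.34 for collagens, 0.43 for complement, 0.36 for tendon and 0.65 for mast cells.

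**Figure D1:**
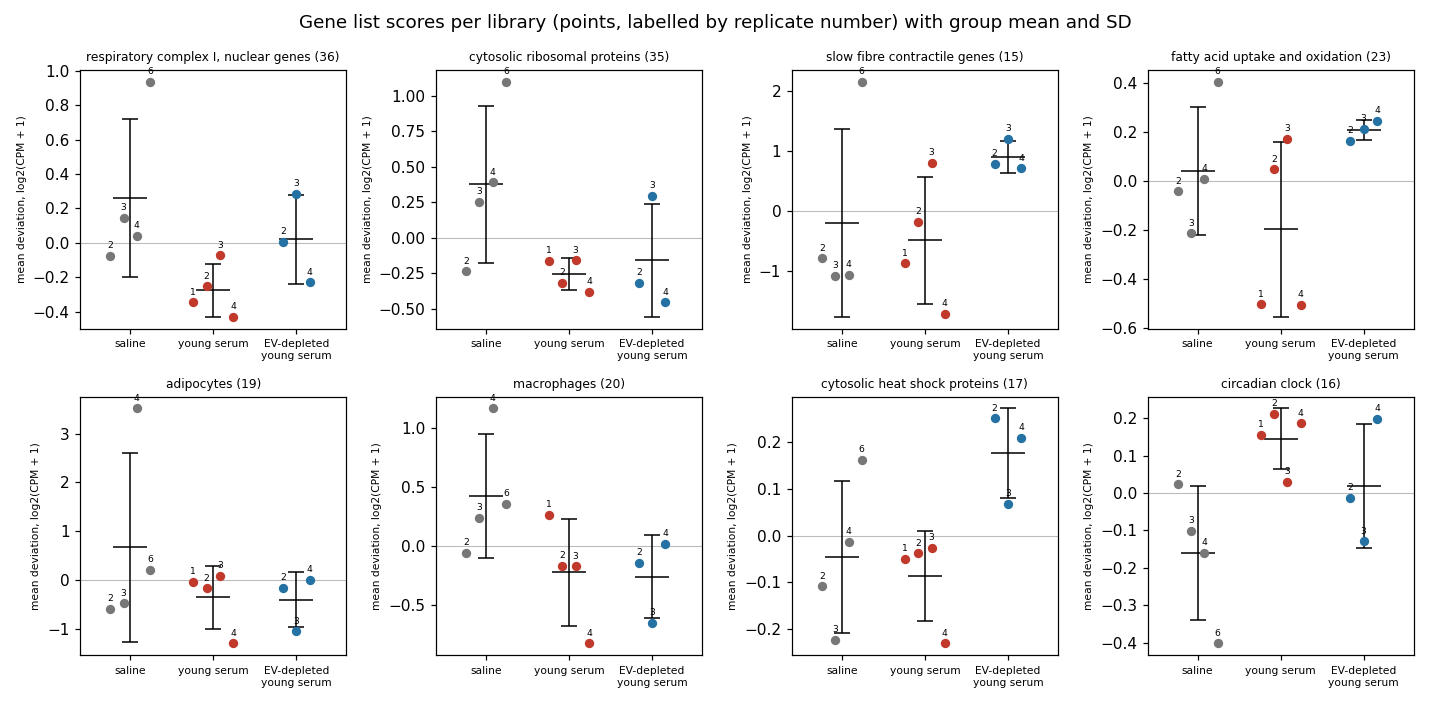
Gene list scores per library for 8 lists, as the mean deviation of the members on the log2(CPM + 1) scale, in saline, young serum and EV-depleted young serum. Points are libraries labelled by replicate number, and bars show mean and SD; saline replicate 6 had a slow fibre score of 2.15 and saline replicate 4 an adipocyte score of 3.52.

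**Figure D2:**
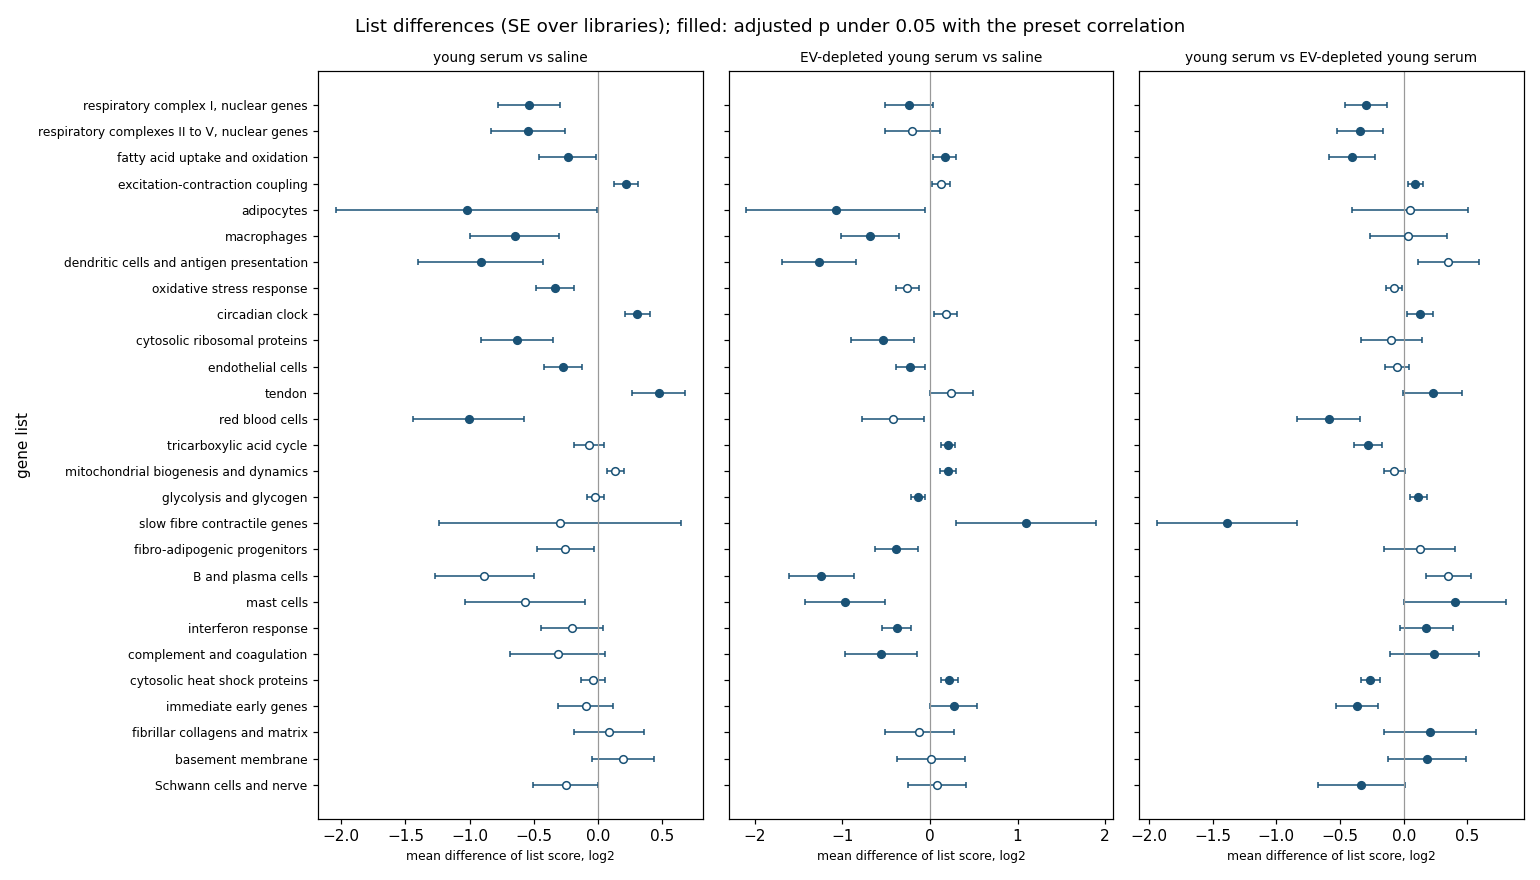
Mean difference of the list scores in log2 units with SE over libraries for the 27 lists called in at least 1 comparison. Filled points had an adjusted p under 0.05 with the preset correlation, and 0 did with an estimated one.

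The 2 serum comparisons share the saline libraries. Across 13187 genes, which are not independent replicates, their fold changes correlated at r = 0.859 (Spearman 0.853), with 84.2% of genes of the same sign. With unchanged groups simulated as noise of each gene's own spread, sharing 1 simulated saline mean, r was 0.7003. Genes vary independently in that simulation, unlike in the libraries, so it does not show how far r or the covariance can vary by chance. With the deviations of the libraries regrouped at random r had a median of 0.527 (middle 95% from -0.180 to 0.878), and 4 of 100 regroupings reached the observed value, which lies inside that range. The covariance was 0.119 against 0.0523 simulated, a difference of 0.0663. With the saline libraries split into pairs, r averaged 0.454 over 6 splits (0.318 to 0.614), with a mean covariance of 0.0745. The genes past the threshold in both young serum comparisons numbered 0. At an unadjusted p under 0.05, 30 genes were higher and 53 lower in young serum than in both other groups, where independent lists give 6.60 and 26.4 and simulated unchanged groups gave 65.2 in all.

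Among the fixed genes, Pax7 of satellite cells averaged 1.23 ± 0.19 CPM in saline, 1.95 ± 0.26 in young serum and 1.76 ± 0.60 in EV-depleted serum, and Myod1 31.6 ± 6.20, 37.1 ± 3.77 and 29.7 ± 3.18. The developmental myosins Myh3 and Myh8 averaged 17.0 ± 25.5 and 6.63 ± 3.11 CPM in young serum and 3.45 ± 4.27 and 3.54 ± 1.35 in saline. Young serum replicate 3 had 55.3 CPM of Myh3 (3.28 to 4.72 in the others) and saline replicate 6 had 9.85 (1.17 to 1.57 in the others); without young serum replicate 3 the log2 difference of Myh3 between the sera was -0.65, against 0.21 with it. Tgfb1 averaged 11.1 ± 6.37, 6.11 ± 0.71 and 5.76 ± 0.87, and Col1a1 74.0 ± 37.9, 94.5 ± 33.3 and 66.8 ± 28.0. Myog, Col3a1, Ppargc1a, Tfam, Cdkn1a, Adipoq, Adgre1 and Ddx3y likewise did not pass in any comparison. Below the filter, Kl, which encodes Klotho, averaged 0.214 ± 0.132, 0.203 ± 0.058 and 0.146 ± 0.106 CPM, with overlapping groups. Cdkn2a, which encodes the senescence-associated p16 and p19 proteins, averaged 1.02 ± 0.47 CPM in saline against 0.167 ± 0.164 in young serum and 0.1005 ± 0.047 in EV-depleted serum, with non-overlapping groups (two-sided exact permutation p = 0.0286 and 0.0571, both 0.257 when adjusted over 18 tests); young serum replicate 2 had 0.412 CPM and the others 0.0765 to 0.104. Ccl2, a monocyte chemokine, averaged 0.589 ± 0.123, 0.240 ± 0.110 and 0.371 ± 0.053, with the same exact p-values. Il6, Mymk and Mki67 overlapped between groups.

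**Figure D3:**
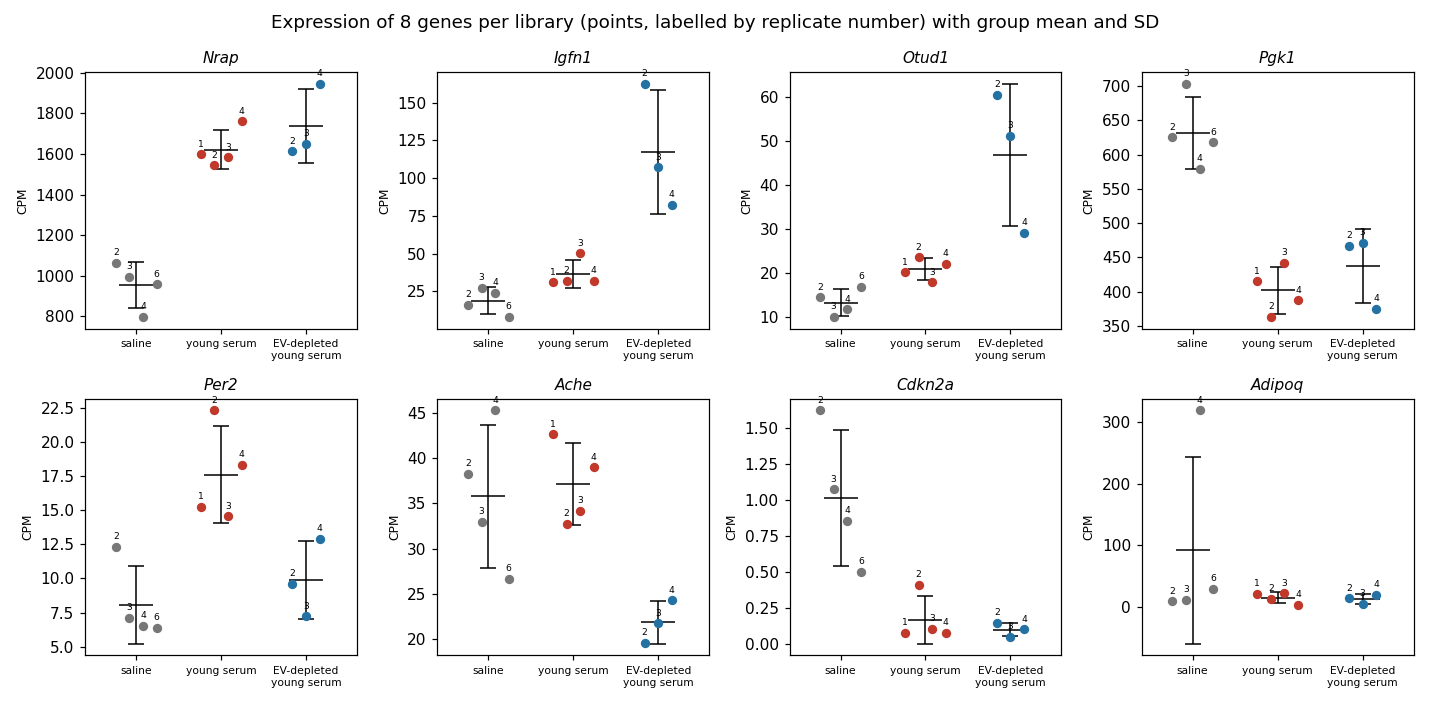
CPM per library for 8 genes in saline, young serum and EV-depleted young serum, with points labelled by replicate number and bars for mean and SD. Igfn1 reached 162.4 CPM in EV-depleted replicate 2 and Adipoq 319.8 CPM in saline replicate 4.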

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

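The tests that left out saline replicate 4 or 6 and the slow fibre covariate were chosen after the result was seen. Of 158 groups of 4 libraries examined, 16 held a library far from the other 3, 10 of them in saline; chance gives about 1 in 20. Saline replicate 4 stood above its group for Adipoq (319.8 CPM), Adgre1 (20.8 CPM), Tgfb1 (20.7 CPM), Dnase2a (10.2 CPM), the immediate early score (0.60) and the median CPM (7.57). Saline replicate 6 stood above for the slow fibre score (2.15), the score of complexes II to V (1.06) and Myh3 (9.85 CPM), and saline replicate 2 for Per2 (12.3 CPM). In young serum, replicate 3 was high for Myh3 (55.3 CPM) and Igfn1 (50.0464 CPM), replicate 2 for Cdkn2a (0.412 CPM), and replicate 4 low for Tgfb1 (5.05 CPM), Tfam (28.4 CPM) and the heat shock score (-0.23).

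The first pattern is the lower immune, adipocyte, ribosomal and respiratory lists in young serum than in saline. Without saline replicate 4 the adipocyte difference was -0.0731 (from -1.02) and the combined immune and adipocyte one -0.28 (from -0.84), so fat in that muscle sample may account for the adipocyte part; the immune part kept -0.43 of -0.71, and other tissue in that library cannot be told apart from a serum effect because the loss is partial. For the 110 ribosomal and respiratory genes, -0.32 of -0.57 was kept without saline replicate 6 and -0.36 after removing the trend of each library on transcript length (48.7% to 70.0% kept when libraries were left out), so neither can be told apart from a serum effect, which stays open and untested.

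The second pattern is the lower oxidative lists in young serum than in EV-depleted serum. With the slow fibre score as a covariate, the difference of the 116 genes was -0.0149 (from -0.33; -12.1% to 20.3% kept when libraries were left out), so the share of slow fibres in the muscle may account for it. This does not separate uneven sampling from an effect of the serum on fibre type. Removing the length trend kept -0.28 (84.7%; 72.8% to 90.9%), a range too wide to exclude a part for length.

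Splits of the libraries into groups of the same sizes bear on the counts. At least as many genes past the threshold as the real 0 came from 35 of 35 splits in each comparison (highest other 10 for young serum against saline, 23 for EV-depleted serum against saline and 0 between the sera), so these counts exclude nothing. At an unadjusted p under 0.05, 2 of 35 splits gave at least the real 2890 (highest other 2962), 7 of 35 at least 1593 (highest other 4312) and 11 of 35 at least 294 (highest other 1010). For lists, 24, 9 and 5 of 35 splits gave at least the real 13, 18 and 18 (highest others 23, 25 and 22). With gene-by-gene array weights, 2 and 3 of 35 gave at least the real 1209 and 520 (highest others 1335 and 1126), while between the sera 1 of 35 gave at least the real 54 (highest other 4). Chance was not excluded for any of these counts. In the last case the 1 split was the real one, the smallest share that 35 splits can give. Many counts were examined without adjustment, and these weights were added after seeing the data. They gave EV-depleted replicate 2 a weight of 5.68, against 0.679 and 0.432 for replicates 3 and 4. In saline they gave replicate 3 a weight of 1.93, against 0.633, 0.221 and 0.297 for replicates 2, 4 and 6.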

How the results depend on the processing

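Upper-quartile scaling, voom weights, gene-by-gene array weights, the exact permutation of list means and leaving out both saline replicates 4 and 6 were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run, since whole reads were not recovered. Genes past the threshold, 0 in all 3 comparisons, became 3441, 1794 and 24 with array weights (whose estimate stopped before convergence) and 1209, 520 and 54 with the gene-by-gene estimate; for EV-depleted serum against saline they became 3 at a mean CPM of at least 5, 2 with TPM, 2 without both saline replicates 4 and 6 and 6 with the replicate block. Leaving out 1 library gave 0 to 251, 0 to 5 and 0 to 0 genes, and 8 to 15, 15 to 21 and 15 to 21 lists. Called lists (13, 18 and 18) became 0, 0 and 0 with an estimated correlation and with fry, and 1, 1 and 2 by exact permutation at an unadjusted p under 0.05 (the lowest adjusted p being 0.327, 0.462 and 0.600); 21 for young serum against saline without a filter; 6 (young serum against saline) and 10 (between sera) with array weights, 5 and 11 with the gene-by-gene estimate; and 11 and 11 with TPM in the 2 comparisons with EV-depleted serum. The 1 list by permutation for EV-depleted serum against saline held embryonic and neonatal contractile genes (exact permutation p = 0.0286), which camera did not call. The overlap of 0 became 6 and 11 with the 2 array weight estimates. The correlation stayed between 0.746 and 0.909. Pairing by sample number was not apparent: same-numbered libraries correlated at -0.277 to 0.2998 over 9 pairs, 2 of 9 correlating best with their own number. So few libraries per group cannot exclude such pairing. Reversed were fatty acid genes with the replicate block (-0.0130) in young serum against saline, where camera's direction changed; adipocytes without both saline replicates 4 and 6 (0.176 for young serum, 0.126 for EV-depleted serum against saline); endothelial genes of EV-depleted serum against saline with array weights (0.0137 and 0.00226); complex I there with the replicate block (-0.0168) and without saline replicate 6 (-0.0168; lowest -0.374, without EV-depleted replicate 3), where again camera's direction changed; and, without EV-depleted replicate 3 between the sera, collagens (-0.110; highest 0.427), basement membrane (-0.0892; highest 0.437) and complement (-0.0331; highest 0.434). Fewer libraries entered the leave-out fits. The replicate block acts as a leave-out too, because only saline replicate 6 and young serum replicate 1 carry their numbers and the block absorbs them. Otherwise the cause was not tested. Of 5902 alternatives of 270 named gene values, 68 had the other sign and 219 passed the threshold. No scaling moved the median of all genes by more than 0.1 on the log2 scale. Values of Kl, Il6 and other genes under 1 CPM were low, and whether depth limited their comparison was not tested.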

Other observations

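The hour of tissue collection test was written before its genes were examined, although the direction of the whole clock list had been seen. Several lists not described above were not called in any comparison. Satellite cell and commitment genes differed by 0.05 ± 0.05 (SE) for young serum against saline, 0.03 ± 0.06 for EV-depleted serum against saline and 0.02 ± 0.04 between the sera. Genes of EV biogenesis differed by -0.14 ± 0.14, -0.12 ± 0.14 and -0.02 ± 0.10, and atrophy and ubiquitin ligase genes by 0.06 ± 0.09, 0.02 ± 0.11 and 0.04 ± 0.08. Fast fibre genes differed by -0.05 ± 0.10, -0.01 ± 0.11 and -0.05 ± 0.08. For EV-depleted serum against saline, 3 of them passed over the list alone, Myh1 higher (log2 difference 1.47) and Casq1 (-0.45) and Pvalb (-0.88) lower. Pvalb also passed over the list alone for young serum against saline (-0.82). In each comparison with saline 1 denervation gene passed over the list alone, Musk with young serum (1.19) and Ankrd1 with EV-depleted serum (1.56). These genes were named after their values were seen.

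The clock list differed by 0.13 ± 0.10 between the 2 sera, with an adjusted p of 0.635 at an estimated correlation and 0.955 by fry and an exact permutation p of 0.257, and no clock gene passed over all genes. Nr1d1 was lower with young serum (-0.44) together with Arntl (-0.71). Of the genes whose values had not been looked at, Per3 (0.58), Dbp (0.36), Tef (0.24) and Ciart (0.12) were higher with young serum, and Clock (-0.23) and Nfil3 (-0.11) lower, while Cry1 was 0.11. Their contrast was 0.40 ± 0.07 (SE), with an exact permutation p = 0.0286, the smallest 35 arrangements give. They belong to the same list and libraries as the clock genes already seen, so this p-value is not independent of those. A difference in the hour of collection is a candidate explanation for this contrast, but the hour is not given in the sources used here. Cry1 moved against the direction that the test had set for it. Without the hours it cannot be told whether Nr1d1 and Cry1 go with this explanation. An effect of the serum on the clock would give the same values and was not tested.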
